A study of Mus musculus with 4 samples.

How the data were processed

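Cells of embryoid bodies from the R1 mouse embryonic stem cell line were measured in 4 single-cell libraries, 1 replicate per group: 8 days of normoxia, 7.33 days of normoxia with 16 h of hypoxia, 10 days of normoxia, and 8 days of normoxia with 48 h of hypoxia. Embryoid bodies were dissociated with Accumax and strained, per the labels' protocols. The deposited files hold raw UMI counts per gene and cell, and the submitters' processing notes name Cell Ranger 7.1.0 and the mm10 build. Whether intronic reads were counted is not given in the sources used here. The values were checked to be whole numbers with a different total in each library. Each file listed the same 32285 gene IDs, of which 32235 matched GENCODE M21, from which coordinates (1-based, mm10) were taken. Of rare symbols given to more than 1 ID, the ID with more UMIs was used.

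Barcodes with at least 500 genes and at most 15% of UMIs from mitochondrially encoded genes were kept, and cells called doublets by Scrublet (run on each library through scanpy 1.11.5) were removed. Scrublet called 5, 1, 9 and 1 cells in normoxia and hypoxia at day 8 and at day 10, 0.158%, 0.0299%, 0.336% and 0.0217%, where loading would give about 2.70%, 2.79%, 2.24% and 3.80%. Doublets left among the kept cells were not measured. An alternative chosen after seeing the data also removed the 86, 93, 60 and 175 cells of highest score. The kept cells held 84709052, 78022581, 62221875 and 76789304 UMIs, with medians of 5392, 4660, 4882 and 3149 genes and 3.95%, 1.85%, 3.92% and 0.562% mitochondrial UMIs per cell. At 20 CPM the exact Poisson interval spans -4.71% to 4.88%, -4.90% to 5.09%, -5.48% to 5.71% and -4.94% to 5.13% of the value, and at 5 CPM about -9.30% to 9.99% in the library of most UMIs and -10.8% to 11.8% in that of fewest.

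UMIs were summed over cells per library, scaled by the library's total of all UMIs to CPM, and compared as the log2 ratio of CPM + 1 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19). Intervals are at 95% and leave out differences between cultures and libraries. Those for a level (exact Poisson), a ratio (exact conditional binomial) and a share (Clopper-Pearson) cover counting error only. That of a list's median (order statistics over members, from 6 members) reflects the spread over members. That of a percentage of genes is exact binomial over genes, which are not independent. The interval of a gene's ratio is of the plain ratio without the pseudocount, so the log2 ratio of CPM + 1 of a low gene can lie outside it. A gene at 0 was set against a floor of 3 counts over the class. No test or p-value was computed, since each group has 1 library and cells are not replicates.

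The comparisons were hypoxia against normoxia at day 8, the same at day 10, and day 10 against day 8 in normoxia. Counts of genes at least 2-fold different and the correlation across genes used genes with a mean of at least 20 CPM over the libraries. For 18 gene lists and 25 lists of cell type markers, the median log2 ratio was taken over members with a mean of at least 5 CPM, and set, as a description, beside 10000 random lists of the same size matched on expression in 20 bins. For HIF targets and glycolysis the median lay at the 100th percentile of these in both hypoxia comparisons, and for mitochondrially encoded, S phase and G2 and M phase lists at the 0th.

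Named genes followed a rule. Symbols beginning with mt-, Rps, Rpl or Gm and a digit, ending in Rik, or naming clones were left out. Of the rest with a mean of at least 20 CPM, the 10 highest and 10 lowest ratios of each hypoxia comparison, the 8 highest and 8 lowest with age, and the 8 of largest shared ratio per direction were named. Up to 4 members of each list with the largest absolute ratio could be named too, with Vegfa, Slc2a1, Pdk1, Bnip3, Egln3, Ldha, Pgk1 and Aldoa whatever their values. Within classes the rule was the 3 highest and 3 lowest ratios among genes of at least 20 CPM and 50 UMIs, without hemoglobin genes and markers of other classes. The groups, comparisons, lists, markers, filters, naming rule for genes and the first 18 alternatives were chosen before the data were examined.

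Cells of all libraries were clustered together on 2000 variable genes chosen within libraries, leaving out genes of hypoxia, glycolysis, cell cycle, stress, dissociation, mitochondria and ribosomal proteins, with 30 principal components, 15 neighbours and Leiden at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). A cluster was named after the marker list with the highest mean log2 fold, if that was at least 1 and at least 3 of its markers were 2-fold higher and seen in 10% of cells. Clusters were set against all others, and those left against the named ones, since most clusters were mesenchymal. Fibroblast, lateral mesoderm, smooth muscle and epicardial lists were merged as mesenchymal, and gut and yolk sac endoderm as endoderm. This naming rule and merging were chosen after seeing the data. The clusters were all named. Clusters 18, 21 and 25 had low depth (0.188, 0.177 and 0.167 times the library's median UMIs) and kept their names because 7, 4 and 2 of their 10 highest genes were own markers. Classes with at least 100 cells in both libraries were compared.

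The steps were tested on simulated data. With 6575 genes, 100 simulated at an absolute log2 ratio of 1 and 100 at 2, the direction was recovered for 100% of each size at day 8 and at day 10; the median recovered sizes were 0.98 and 1.97 at day 8 and 0.99 and 1.95 at day 10, and intervals covered the truth for 95.3% and 95.1% of genes. With 10598 genes, 6% of 200 random lists of 30 lay beyond the 95% range of matched lists in either comparison, and of lists shifted by 0.5, 100% did at day 8 and 76.5% at day 10. Simulated cells, drawn at real depths from the mean profile of an assigned class, were given that class for 98.4% to 100%. They were treated as 1 library and held no subtypes, doublets or differences between libraries. This recovery thus does not show that the names of real cells are right.

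Alternatives were TMM scaling (edgeR 4.0.16 in R 4.3.3; factors 1.18, 1.01, 1.09 and 0.768), cells of equal weight, a total without mitochondrial, ribosomal protein and hemoglobin genes, cells thinned to 3061 UMIs, pseudocounts of 0.1 and 10 CPM, no filter on low genes, a mean of at least 50 CPM, lists without their most extreme member, and class shares held constant. For cells and clusters they were all deposited barcodes, at least 1500 genes with at most 10% mitochondrial UMIs, doublet calls kept, resolutions of 0.5 and 2, response genes kept, each library clustered alone, and 4000 variable genes. Besides the removal of highest doublet scores, cells of at least 10000 UMIs and ratios centred on the median of all genes were added after seeing the data. Thinning left out 53, 97, 117 and 462 cells. Figures were drawn with matplotlib 3.10.9. Reads, splicing and phase calls per cell were not analysed here.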

Results

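Embryoid bodies, spheres of differentiating cells, were grown from the R1 line of mouse embryonic stem cells. The RNA of their dissociated cells was counted per cell in 4 droplet libraries of the 10x Genomics kind. Each library was its own condition: 8 days in normoxia, the same age with hypoxia for the last 16 h, 10 days in normoxia, and the same age with hypoxia for the last 48 h. The oxygen level was not given in the sources used here. The libraries held 3374, 3489, 2802 and 4746 barcodes and 85379390, 78354814, 63117306 and 77012257 unique molecular identifiers (UMIs) in that order. Of the barcodes, 3163, 3344, 2670 and 4615 were kept as cells, with medians of 23034, 18838.5, 20306 and 12800 UMIs per cell. With 1 library per condition, none of the differences below has a replicate check, and library and condition cannot be told apart. Intervals are at 95% and leave out differences between cultures. Those of levels, ratios and shares cover counting error only. Those of list medians and of percentages of genes reflect the spread over genes, which are not independent.

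The first question was how transcript levels differed after 16 h of hypoxia at the end of 8 days. Genes that hypoxia-inducible factor (HIF) is known to switch on were higher in the hypoxic library. Of 51 measured HIF targets outside glycolysis, 42 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 1.59 (interval over members 1.24 to 2.03). The largest difference among all named genes was in Egln3, which encodes the prolyl hydroxylase that marks HIF for destruction. It was at 7.22 CPM (counts of a gene scaled to the same total in each library; Poisson interval 6.66 to 7.82) in normoxia and 62.2 (60.5 to 64.0) in hypoxia, a log2 ratio of 2.94. Of 17 glycolysis enzymes, 14 were at least 1.5-fold higher and 1 lower (median 1.60, interval 1.40 to 1.76). Transcripts for DNA replication and those encoded in the mitochondrial genome were lower. On the mm10 assembly Egln3 (ENSMUSG00000035105) lies on chromosome 12 from 54178981 to 54203860, minus strand. The angiogenic growth factor gene Vegfa (ENSMUSG00000023951) lies on chromosome 17 from 46016993 to 46032369, minus strand.

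Among the HIF targets, Stc2 (a secreted glycoprotein; log2 ratio 2.93), Ero1l (disulfide bond formation in the endoplasmic reticulum; 36.2 CPM in normoxia and 269 in hypoxia, 2.86) and Ankrd37 (2.83) followed Egln3. The growth-arrest gene Ndrg1 was at 30.5 and 218 CPM (2.80), the mitophagy receptor gene Bnip3 at 57.0 and 266 (2.20) and Vegfa at 21.1 and 77.3 (1.82). The pyruvate dehydrogenase kinase gene Pdk1 was at 26.7 and 98.7 (1.85) and the glucose transporter gene Slc2a1 at 345 and 798 (1.21). In glycolysis, the phosphofructokinase genes Pfkp and Pfkl had log2 ratios of 2.46 and 2.01, Pgk1 2.33, Aldoc 2.24, Ldha 1.76 and Aldoa 1.40. The exception was Bpgm (-0.67). The highest ratios also held Tmem45a (2.66), the lipolysis inhibitor gene G0s2 (2.64), the stress-response gene Ier3 (2.58), the neurokine gene Tafa2 (2.54), the cytochrome c oxidase isoform gene Cox4i2 (2.51), Ndrg2 (2.49) and the collagen prolyl hydroxylase gene P4ha2.

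Of the oxygen sensing components, 4 of 9 were at least 1.5-fold higher and 1 lower (median 0.20). Egln1, a further HIF prolyl hydroxylase gene, had a log2 ratio of 2.45 and Epas1, which encodes HIF-2 alpha, -0.75. Of 18 chromatin oxygenases that use 2-oxoglutarate, 6 were higher and 0 lower by 1.5-fold (median 0.33). Among them were the histone demethylase genes Kdm3a (1.27) and Kdm4b (1.13) and the DNA demethylation gene Tet2 (0.94). Of 19 collagens and collagen-modifying enzymes, 6 were higher and 0 lower (median 0.34), with P4ha1 (1.77), the crosslinking enzyme gene Lox (1.65) and Plod2 (1.20) beside P4ha2. Of 14 angiogenic genes 5 were higher and 0 lower (median 0.26, below 0 with a mean of at least 50 CPM), with Adm (2.13) and the VEGF receptor gene Flt1 (1.04). The lists of this paragraph share members with the HIF targets: Egln1, Egln3, Kdm3a, P4ha1, P4ha2, Plod2, Lox, Loxl2, Vegfa, Adm and Cxcr4. Their counts of higher genes are thus in part the same genes counted again.

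Among the 13 mitochondrially encoded transcripts, 10 were at least 1.5-fold lower and 0 higher (median -1.14, interval -1.35 to -0.58). They ranged from mt-Nd3 (-2.46) and mt-Nd4l (-1.44) to mt-Nd6 (-0.18, which was 0.04 with TMM scaling). These took 3.82% of UMIs in normoxia and 2.01% in hypoxia. Nuclear genes of oxidative phosphorylation were lower by less (median -0.29, or -0.062 with TMM scaling; 8 of 74 at least 1.5-fold lower and 0 higher), with the ATP synthase genes Atp5k (-1.02) and Atp5g1 (-0.70) and cytochrome c (Cycs, -0.90). The citric acid cycle had a median of -0.20, 0.02 with TMM scaling, with 1 of 20 members lower by 1.5-fold (Idh3a, -0.69).

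Of 42 S phase genes, 34 were at least 1.5-fold lower and 0 higher (median -0.88, interval -1.01 to -0.78). Among them were the ribonucleotide reductase gene Rrm2 (56.3 and 18.5 CPM, -1.55), Cdca7 (-1.48), the DNA methylation maintenance gene Uhrf1 (-1.31) and the helicase gene Mcm6 (-1.25). G2 and M phase genes were lower by less (median -0.40, or -0.18 with TMM scaling; 12 of 52 lower and 1 higher by 1.5-fold), for example Hmgb2 (-0.97) and Cdc25c (-0.88). The lowest ratios of all also held the macrophage mannose receptor gene Mrc1 (-1.79), the complement gene C1qb (-1.30), the endodermal trypsin inhibitor gene Spink1 (-1.66), the RNA helicase gene Ddx21 (-1.52), Pcp4 (-1.48), Sdk2 (-1.28) and the imprinted gene Phlda2 (-1.26). Markers of the same cell types were lower too. Macrophage markers had a median of -0.63 (7 of 13 lower by 1.5-fold) and yolk sac endoderm markers -1.08 (5 of 7), with the apolipoprotein genes Apoc2 (-2.19), Apob (-1.94) and Apoa1 (-1.64).

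The median of all genes at this age was -0.07. The unfolded protein and integrated stress response was at 0.10 (5 of 22 higher by 1.5-fold, with Trib3 at 0.81 and Ddit3 at 0.78) and immediate early and dissociation genes were at -0.05, or 0.16 with TMM scaling (1 of 16 higher, Ier3, and 1 lower, Hspa1a at -1.01). The p53 targets were at -0.08, or 0.14 with TMM scaling (2 of 16 lower, Pmaip1 at -0.86 and Gtse1 at -0.72) and heme biosynthesis at -0.08, or 0.14 with TMM scaling (Cpox 0.94 and Alad -0.65 among 2 higher and 2 lower of 12). Cholesterol biosynthesis was at -0.27, or -0.045 with TMM scaling (3 of 21 lower by 1.5-fold, among them Hsd17b7 at -0.84 and Mvk at -0.68), hemoglobin at -0.19 (0.03 with TMM scaling) and the 3 measured interferon response genes at -0.72 (-0.28 with no filter on low genes). Among 6575 genes with a mean of at least 20 CPM, 115 were at least 2-fold higher and 60 lower, 65.7% higher. TMM scaling shifted the median of all genes by 0.23 and made this 191 and 14 (93.2%). Other settings gave 80.2% (85 and 21, pseudocount of 10 CPM), 80.5% (70 and 17, mean of at least 50 CPM), 77.5% (138 and 40, ratios centred on the median of all genes) and 40.5% (243 and 357, no filter on low genes).

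**Figure D1:**
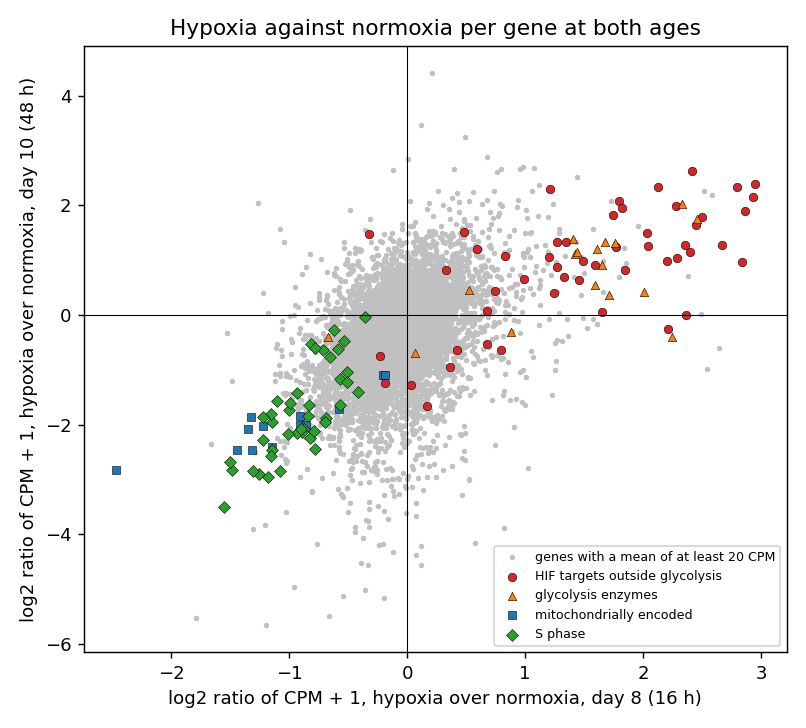
Log2 ratio of CPM + 1 of each gene with a mean of at least 20 CPM, hypoxia over normoxia, at day 8 (across) and at day 10 (up), with the members of 4 lists, from 5 CPM, marked. HIF targets and glycolysis enzymes had medians of 1.59 and 1.60 at day 8 and 1.06 and 0.90 at day 10, and the medians of mitochondrially encoded and S phase transcripts lay below 0 in both comparisons.

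The next comparison asked how cultures of 10 days differed after 48 h of hypoxia. HIF targets were higher again (37 of 51 by at least 1.5-fold, 7 lower; median log2 ratio 1.06, interval 0.82 to 1.28), and so were glycolysis enzymes (9 of 17, with 1 lower; median 0.90, interval 0.37 to 1.32, or 1.40 with TMM scaling). Genes of replication, mitosis and the mitochondrial genome were lower by more than at day 8, and so were many genes of mesenchymal and macrophage identity. Among contractile and stress-response genes, which went both ways, higher ones were Tagln, which encodes the actin-binding protein transgelin, at 575 CPM in normoxia and 3655 in hypoxia (2.67), and the stress-induced transcription factor gene Atf4 at 73.8 and 274 (1.88).

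Egln3 was at 11.7 CPM (10.9 to 12.6) in normoxia and 65.9 (64.1 to 67.7) in hypoxia (2.39). Vegfa was at 37.3 and 147 (1.95), Slc2a1 at 190 and 936 (2.29), Bnip3 at 63.6 and 127 (0.98) and Pdk1 at 26.7 and 47.8 (0.82). Among other HIF targets, the adenylate kinase gene Ak4 (2.63), Ndrg1 (2.33), the vasodilator gene Adm (2.32) and Stc2 (2.15) had the higher ratios. The metallothionein genes Mt1 (-0.95) and Mt2 (-1.25) were lower. In glycolysis, Pgk1 (2.02), Pfkp (1.76), Aldoa (1.39), Pkm (1.33) and Ldha (1.32) were higher, Pfkl was at 0.41, and Aldoc was at -0.41, or 0.05 with TMM scaling.

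Among named genes with a mean of at least 20 CPM, the highest ratio was in Slc5a3, the inositol transporter gene (15.1 CPM, interval 14.1 to 16.1, in normoxia; 177, 174 to 180, in hypoxia; 3.47). Slc5a3 (ENSMUSG00000089774; chromosome 16, 92058322 to 92087473, plus strand) lies inside the annotated span of the mitochondrial ribosomal protein gene Mrps6 (2.63), also among the highest. They share 29152 bases, so how UMIs divide between this pair is uncertain. Next came the collagen gene Col8a1 (5.64 and 61.6 CPM, 3.24), the histone gene Hist1h4i (2.89, of a family of near-identical genes that can share reads), the chaperone gene Hspa4l (2.84) and the small nucleolar RNA host genes Snhg16 (2.70) and Snhg12 (2.68). The mechanosensitive gene Ankrd1 (2.67) and the kinase gene Pim3 (2.66) followed. Of 22 genes of the unfolded protein and integrated stress response, 13 were higher and 4 lower by 1.5-fold (median 0.81, interval -0.24 to 1.33, or -0.0020 with a mean of at least 50 CPM), with Nupr1 (2.61), Trib3 (2.47) and Ddit3 (1.86) highest. For p53 targets, 7 of 16 were higher and 0 lower (median 0.38, or 0.87 with TMM scaling), with the apoptosis genes Bbc3 (1.94) and Pmaip1 (1.42) and Mdm2 (0.92). Smooth muscle markers split, with Acta2 (1.75) and Cnn1 (2.06) higher beside Tagln and Mylk (-1.60) lower. Of the list, 4 of 8 were higher and 4 lower.

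All 13 mitochondrially encoded transcripts were at least 1.5-fold lower (median -2.02, interval -2.46 to -1.73), with mt-Nd3 at -2.83, mt-Atp8 at -2.47 and mt-Atp6 at -2.41. They took 4.05% of UMIs in normoxia and 1.11% in hypoxia. Nuclear genes of oxidative phosphorylation had a median of -0.58 (37 of 74 lower by 1.5-fold, 0 higher; Ndufb7 -1.46, Ndufa5 -1.43), or -0.08 with TMM scaling. Citric acid cycle genes were at -0.66 (11 of 20 lower, 0 higher; Idh2 -1.80, Suclg2 -1.57), or -0.16 with TMM scaling. Of 42 S phase genes 38 were lower and 0 higher by 1.5-fold (median -1.87, interval -2.14 to -1.61, or -1.07 with a pseudocount of 10 CPM), such as Rrm2 (40.6 and 2.67 CPM, -3.50), the DNA polymerase gene Pola1 (-2.95), Mcm6 (-2.90) and Uhrf1 (-2.86). Of 52 G2 and M phase genes 42 were lower and 0 higher (median -1.33), such as the proliferation marker gene Mki67 (-3.17) and Cenpf (-2.27).

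The lowest ratio was in Angptl7 (ENSMUSG00000028989; chromosome 4, 148495183 to 148500460, minus strand), a secreted angiopoietin-like protein gene. It was at 73.5 CPM (71.3 to 75.6) in normoxia and 0.482 (0.339 to 0.664) in hypoxia, a log2 ratio of -5.65. The macrophage gene Mrc1 (ENSMUSG00000026712; chromosome 2, 14229392 to 14332057, plus strand) followed at 73.7 and 0.612 CPM (-5.53). Next came the metalloprotease gene Adam12 (-5.49), Rtl4 (-5.13), Tenm4 (-5.01), Hsd11b2 (-4.96), Kcnb2 (-4.57), Nrxn3 (-4.56) and the netrin receptor gene Unc5c (-4.52). Among 14 fibroblast markers 10 were lower and 0 higher by 1.5-fold (median -1.28), with the proteoglycan genes Dcn (682 and 99.5 CPM, -2.77) and Lum (-2.22) and Col6a3 (-2.43). All 7 epicardial markers were lower (median -1.86), with Muc16 (-3.98), Aldh1a2 (-2.94) and Upk3b (-2.03). Macrophage markers had a median of -1.97 (13 of 13 lower), with C1qa (-3.97), C1qb (-3.90) and C1qc (-3.86) beside Mrc1. Hemoglobin genes were at -4.17 (6 of 7 lower, with Hbb-bs -5.16 and Hbb-y -4.37, whose near-identical paralogs can share reads). The hemoglobin value rests on few cells. Erythroid-like cells numbered 11 in normoxia, with 33624 hemoglobin UMIs, and 10 in hypoxia, with 1253. Their median depths were 14839 and 1895.5 UMIs. Heme biosynthesis was at -0.98, or -0.074 with a mean of at least 50 CPM (9 of 12 lower and 1 higher, with Alad -2.24 and Cpox 2.09).

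Other lists went both ways at day 10. Oxygen sensing components had a median of 0.40, or -0.11 with no filter on low genes (3 of 9 higher, 4 lower by 1.5-fold; Egln1 1.65, Hif3a -1.28, Egln2 -0.96). Chromatin oxygenases were at 0.13, or 0.62 with TMM scaling (5 of 18 higher, 3 lower; Kdm3a 0.88, Kdm4a -1.25), and immediate early genes at -0.03 (4 of 16 higher, 5 lower; Hspa1a 2.72, Ier3 2.19, Dusp1 2.07, Egr1 -1.59), or 0.54 with TMM scaling. Collagens and their enzymes had a median of -0.29 (5 of 19 higher, 7 lower), with P4ha2 (1.79) and P4ha1 (1.24) above and Col6a2 (-2.52) and Col1a2 (2129 CPM in normoxia and 502 in hypoxia, -2.08) below, where TMM scaling put the median at 0.19. Angiogenic genes were at -0.47 (6 of 14 higher, 7 lower), with the growth factor gene Pdgfb (2.01) above and the receptor gene Kdr (-3.86) and Angpt1 (-3.11) below, where TMM scaling put the median at 0.55. Cholesterol biosynthesis was at -0.65 (12 of 21 lower, 0 higher; Acat2 -1.66, Hsd17b7 -1.65), or -0.16 with TMM scaling. The 3 interferon genes were at -1.35 (-0.59 with no filter on low genes). Among 6575 genes, 318 were at least 2-fold higher and 1433 lower, 18.2% higher. This split depended on the scaling. TMM shifted the median of all genes by 0.50 and gave 976 and 653 (59.9%) among genes filtered on TMM-scaled levels, and centring on the median of -0.33 gave 664 and 867 (43.4%). The makeup of the UMIs differed alongside. Ribosomal protein genes took 21.8% in normoxia and 30.8% in hypoxia, the 50 most abundant genes 21.2% and 28.4%. The nuclear RNA Malat1 was at 16092 and 27236 CPM.

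Both hypoxia comparisons were set side by side to ask which genes differed after either exposure, since they share no library. The log2 ratios correlated across the 6575 genes with Pearson r = 0.44 and Spearman rho = 0.44, where genes are not independent replicates. At least 2-fold higher in both were 57 genes, where 5.56 would be met if the lists were independent, and 47 were lower in both, where 13.1 would be met. In opposite directions, 4 were higher at day 8 and lower at day 10, and 3 the reverse. Of the 115 genes higher at day 8, 93 had a log2 ratio above 0 at day 10. At a threshold of 1.5-fold, 155 were higher in both, led by Ak4 (2.41 at day 8 and 2.63 at day 10), Egln3, Ndrg1 and Cox4i2 (2.51 and 2.25). In turn 316 were lower in both, led by Rrm2, Uhrf1, Sdk2 (-1.28 and -2.51) and the helicase genes Mcm6 and Mcm2 (-1.22 and -1.86).

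The normoxic libraries of 8 and 10 days give the difference of age that both hypoxia comparisons sit on. Macrophage markers were higher at 10 days, and hemoglobin genes and markers of yolk sac and gut endoderm were lower. The coagulation factor gene F13a1, which macrophages express (ENSMUSG00000039109; chromosome 13, 36867178 to 37050244, minus strand), was at 6.45 CPM (5.92 to 7.01) at 8 days and 89.7 (87.3 to 92.0) at 10 days (log2 ratio 3.61). All 13 macrophage markers were higher by at least 1.5-fold (median 2.33), with C1qa (3.94), C1qc (3.53), Mrc1 (3.30) and C1qb (2.99). The lowest was Nepn (ENSMUSG00000038624; chromosome 10, 52388972 to 52404625, plus strand), an endodermal proteoglycan gene, at 51.8 and 2.65 CPM (-3.85).

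With age the matrix genes Ogn (2.87) and Lox (2.71), Angptl7 (2.64), the cadherin gene Cdh13 (2.63) and the neural gene Brinp1 (2.58) were also among the highest. Of the immediate early list, 12 of 16 genes were higher and 1 lower by 1.5-fold (median 1.10; Fosb 2.32, Nr4a1 1.90), a list that includes genes induced by dissociation. Lower were the embryonic globins Hbb-bh1 (-3.75), Hba-x (-3.60) and Hbb-y (-3.05), the endodermal genes Spink1 (-3.40), Ttr (-3.38) and Pyy (-3.41), the appetite hormone gene Ghrl (-2.94) and the adhesion gene Emb (-2.71). Hemoglobin had a median of -3.05 (7 of 7 lower) and erythroid markers -2.21, but when shares of cell classes were held constant these were 0.12 and 0.20. Such values rest on few cells, here and for the cardiomyocyte markers below. At 10 days in normoxia, 11 erythroid-like and 9 cardiomyocyte-like cells were kept. Yolk sac endoderm markers had a median of -2.68 (6 of 7 lower), gut endoderm -1.99 (7 of 7) and cardiomyocyte markers -1.75, or 0.31 with shares of cell classes held constant (8 of 12 lower, 1 higher; Myl7 -2.58, Tnnc1 -2.48). Cholesterol biosynthesis was at -1.01 (17 of 21 lower, 0 higher; Mvk -1.19) and the stress-response list at -0.54 (10 of 22 lower, 2 higher; Asns -1.76).

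HIF targets (0.11; 8 of 51 higher and 8 lower), glycolysis (0.01, or -0.11 with a mean of at least 50 CPM; 1 higher and 1 lower of 17), oxidative phosphorylation (-0.17, or -0.042 with TMM scaling), mitochondrially encoded transcripts (0.18; mt-Nd6 1.10) and the citric acid cycle (-0.05, or 0.07 with TMM scaling) had medians within 0.2 of 0 with age. Oxygen sensing (0.13), chromatin oxygenases (0.18), p53 targets (0.03) and collagens (0.07) did too. Across the alternatives some passed 0.2, up to 0.25 for oxygen sensing, 0.30 for chromatin oxygenases and 0.44 for p53 targets. Mitochondrially encoded transcripts reached 0.30 and HIF targets 0.22. S phase was at -0.40 (8 of 42 lower, 1 higher) and G2 and M phase at -0.28, or -0.16 with TMM scaling (5 of 52 lower, 0 higher). Heme biosynthesis was at -0.43 (0.04 when shares of cell classes were held constant, with 11 erythroid-like cells at 10 days). Angiogenic genes were at 0.40 (4 of 14 higher, 1 lower) and interferon response at 1.17, or 0.48 with no filter on low genes (2 of 3 higher; Ifitm3 1.47). Of 6575 genes, 173 were at least 2-fold higher and 113 lower, 60.5% higher, or 73.2% with TMM scaling (210 and 77), which shifted the median of all genes by 0.12.

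The other marker lists, as medians at day 8, day 10 and with age, were as follows. Values with shares of cell classes held constant that involve normoxia at day 10 rest on few cells of these types. That library held 11 erythroid-like, 9 cardiomyocyte-like and 2 endothelial-like cells. Cardiomyocyte markers were at -0.48, 0.45 (-0.99 with shares of cell classes held constant) and -1.75. Lateral mesoderm markers were at -0.09 (0.14 with TMM scaling), -0.54 and -0.16 (0.23 with a mean of at least 50 CPM). Smooth muscle markers were at 0.12 (below 0 with no filter on low genes), 0.42 (-0.66 without the most extreme member) and -0.27. Endothelial markers were at 0.15 (-0.08 with cells of equal weight), -0.75 and -0.46 (0.27 with shares of cell classes held constant). Megakaryocyte markers were at -0.05 (0.16 with TMM scaling), -0.56 and -0.58 (1.24 with a mean of at least 50 CPM). Gut endoderm markers were at -0.28 and -1.04, or 0.58 and 0.83 with a mean of at least 50 CPM, and at -1.99 with age. Parietal endoderm markers were at 0.11, -0.31 (0.17 with TMM scaling) and -0.27. Erythroid markers were at 0.01 (-0.28 with shares of cell classes held constant; -0.0063 by a total without mitochondrial, ribosomal protein and hemoglobin genes), -2.28 and -2.21 (0.20 with those shares held constant). Hemogenic, neural, neural crest, ectodermal, nephric, trophoblast and skeletal muscle lists had fewer than 6 members at 5 CPM and are left out here. Fibroblast and epicardial markers had day 8 medians of -0.18 (above 0 with TMM scaling) and 0.35 and age medians of 0.34 and 0.86, and yolk sac endoderm was at -1.12 at day 10. Pluripotent, primitive streak, paraxial mesoderm, mast cell and germ cell markers had no member at 5 CPM.

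Shares of cell classes were compared to see how the makeup of the cultures differed. Mesenchymal-like cells, named from fibroblast markers such as Col1a1, Col3a1, Dcn and Postn, made up 84.9% (Clopper-Pearson interval 83.6 to 86.1), 86.8% (85.6 to 87.9), 89.5% (88.2 to 90.6) and 93.5% (92.7 to 94.2) of cells in normoxia and hypoxia at day 8 and normoxia and hypoxia at day 10. With all deposited barcodes clustered anew the direction at day 10 turned, with 84.8% in normoxia and 71.0% in hypoxia. That hypoxic library held 4746 barcodes, of which 4615 were already kept, so the added barcodes are too few for this fall. Most of it is of kept cells that lost the name, which is thus unstable for part of that library. At day 8 the log2 ratio was -0.0051 instead of 0.031 with each library clustered alone. The name is weak for clusters 2 and 17, with 1028 and 287 hypoxic cells of day 10: none of their 10 highest genes was a marker of the list, and the mean log2 fold of the markers was 1.07 and 1.61. That fold was also low in clusters 6 (1.36, 754 hypoxic cells of day 10) and 7 (1.53, 715 such cells), with 1 and 4 markers among their 10 highest genes. Endoderm-like cells (Ttr, Rbp4, Spink1) made up 7.15%, 5.23%, 2.32% and 1.19%. The ratio of hypoxia to normoxia was 0.732 (0.598 to 0.896) at day 8 and 0.513 (0.350 to 0.750) at day 10, where median UMIs were 19626 and 6358. With cells of at least 10000 UMIs the day 10 log2 ratio was -1.69 instead of -0.96, and with each library clustered alone that at day 8 was -0.79 instead of -0.45. Macrophage-like cells (F13a1, Mrc1, Tyrobp) made up 1.61%, 1.14%, 6.85% and 2.58%. The ratios were 0.705 (0.451 to 1.09) at day 8 and 0.376 (0.296 to 0.476) at day 10, with 19532 and 12278 median UMIs, and 4.25 with age (log2 ratio 2.09, 1.63 to 2.57).

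Erythroid-like cells (Hbb-y, Hba-x, Alas2) made up 3.45%, 4.55%, 0.412% and 0.217%. It was 1.32 times as large a share in hypoxia at day 8 (1.02 to 1.70) and 0.120 times as large at 10 days as at 8 days in normoxia (0.0580 to 0.222). The log2 ratio at day 8, 0.40, was 0.12 in cells of at least 10000 UMIs (3.02% in hypoxia and 2.78% in normoxia) and 0.63 with each library clustered alone. At day 10 there were 11 and 10 such cells. With each library clustered alone the direction at day 10 turned, with shares of 0.787% in normoxia and 1.21% in hypoxia (log2 ratio 0.63 instead of -0.93), and the log2 ratio with age was -1.89 instead of -3.06. Megakaryocyte-like cells (Pf4, Itga2b, Gp9) made up 1.11%, 0.927%, 0.412% and 0.953% and cardiomyocyte-like cells (Actc1, Myl7, Myh6) 0.759%, 0.419%, 0.337% and 0.932%. Endothelial-like cells (Cdh5, Emcn, Cldn5) made up 0.569%, 0.538%, 0.0749% and 0.498%, and pluripotent-like cells (Dppa5a, Pou5f1, Utf1) 0.474%, 0.449%, 0.112% and 0.130%. At day 10 the ratios were 2.31 (1.18 to 4.97) for megakaryocyte-like and 2.76 (1.33 to 6.45) for cardiomyocyte-like cells, where the normoxic library held 11 and 9 of them with medians of 4043 and 1685 UMIs, against 2993.5 and 9438 in hypoxia. The former changed sign under a stricter cell filter (log2 ratio -0.11). For cardiomyocyte-like cells the log2 ratio at day 10, 1.47, was 3.30 under that filter. Endothelial-like cells numbered 2 and 23, and their share in hypoxia was 0.173% with doublet calls kept or at resolution 2. The pluripotent-like class was not found with 4000 variable genes.

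**Figure D2:**
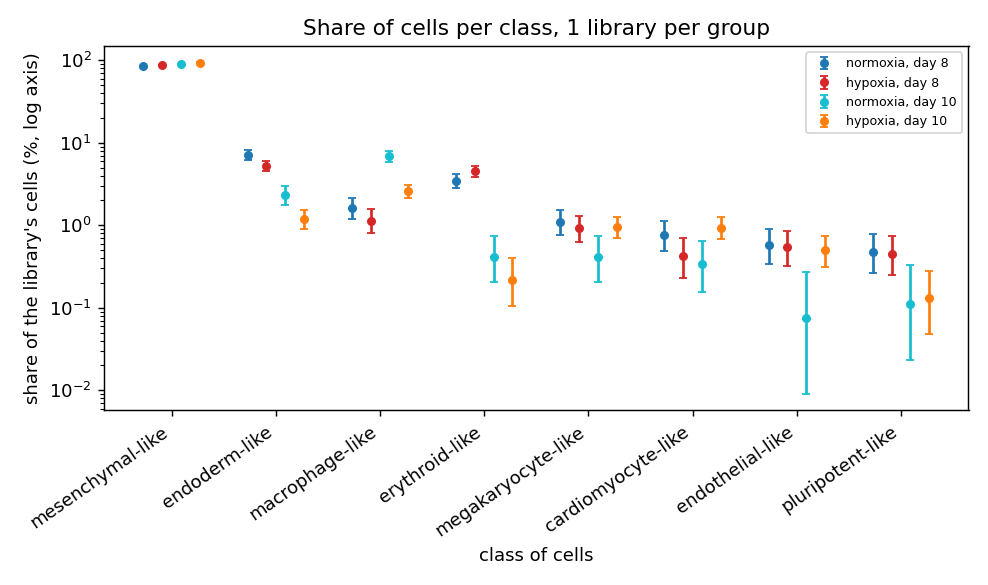
Share of each library's cells (percent, log axis) in each named class, with Clopper-Pearson intervals. Mesenchymal-like cells made up 84.9% to 93.5%, and macrophage-like cells had their largest share, 6.85%, in normoxia at day 10.

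Levels were then compared within classes of at least 100 cells in both libraries. This holds the class constant, but not subtypes within it: mesenchymal-like clusters were often mostly of a single library, also at day 8 (cluster 5, 96.1% hypoxia; cluster 11, 86.1% hypoxia; cluster 1, 82.9% normoxia). In mesenchymal-like cells at day 8 (2901 hypoxic and 2685 normoxic cells), 41 of 50 HIF targets were higher and 0 lower by 1.5-fold (median 1.56, interval 1.21 to 2.15). In the same class Egln3 (3.15), the histocompatibility gene H2-K1 (3.04, with near-identical paralogs) and Ero1l (2.98) were the highest genes and Rrm2 (-1.67), Pcp4 (-1.55) and Ddx21 (-1.49) the lowest. Glycolysis had a median of 1.76, mitochondrially encoded transcripts -1.15, S phase -0.97 (39 of 42 lower) and G2 and M phase -0.43. At day 10 (4315 and 2389 cells), where the largest clusters were mostly of a single library (99.2% of cluster 0 from hypoxia, 98.8% of cluster 9 from normoxia), HIF targets had a median of 1.17 (38 of 49 higher, 4 lower), glycolysis 1.00, mitochondrially encoded transcripts -2.10, S phase -1.88 and G2 and M phase -1.36. The galectin gene Lgals3 (1.36 CPM in normoxia and 65.2 in hypoxia, 4.81), Slc5a3 (3.47) and Col8a1 (3.17) were highest and Angptl7 (-5.77), Adam12 (-5.61) and Rtl4 (-5.22) lowest. With age, where most cells of the later library lay in clusters of their own (at least 97.4% of clusters 9, 10, 13 and 14), Cdh13 (3.05), Ogn (2.81) and Lox (2.64) were highest in this class, and the glycosyltransferase gene B3gnt5 (-2.36), Tdo2 (-2.27) and Tenm2 (-2.20) lowest.

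In endoderm-like cells at day 8 (175 hypoxic and 226 normoxic), HIF targets had a median of 1.43 (41 of 49 higher, 4 lower), glycolysis 1.16 and mitochondrially encoded transcripts -1.25. P4ha2 (3.36), Pfkp (3.31) and Ier3 (3.29) were highest. The proliferation lists lay nearer 0 than in mesenchymal-like cells at day 8: S phase at -0.11, or -0.010 without the highest doublet scores (1 of 42 lower and 1 higher by 1.5-fold) and G2 and M phase at 0.05. At day 10 this was not seen in the 55 hypoxic and 62 normoxic endoderm-like cells. There the S phase share of UMIs in hypoxia was 0.327 times that in normoxia (0.297 to 0.359), against 0.333 in mesenchymal-like cells. For G2 and M phase it was 0.399 against 0.471. Both endoderm-like groups of day 10 were below the 100 cells asked of a class, and their clusters differed. Cluster 15 held 18 hypoxic and 50 normoxic cells, and cluster 21, of low depth, 37 and 12. These day 10 ratios thus do not hold the subtype constant. At day 8, cholesterol biosynthesis was above 0 in endoderm-like cells (0.43, interval 0.17 to 0.54, with 4 of 21 higher and 2 lower). This difference between classes was not tested. The antiviral membrane protein gene Ifitm3 (-2.57), the apolipoprotein gene Apoc2 (-2.20) and Mt2 (-2.12) were lowest in endoderm-like cells at day 8. The fibrillar collagens Col1a1, Col1a2 and Col3a1 together were at 271 CPM (258 to 284) in normoxia and 499 (479 to 520) in hypoxia in this class at day 8. Transcripts from mesenchymal-like cells, which had higher HIF targets in hypoxia too, were thus not excluded from these ratios. In erythroid-like cells at day 8 (152 and 109), HIF targets had a median of 1.71 (41 of 46 higher, 0 lower), glycolysis 1.08, S phase -0.83 and G2 and M phase -0.75. Highest were Ptprd (4.15), Ghr (3.97) and Ptprk (3.92), and lowest Dusp1 (-2.68), Cldn13 (-2.15) and Ptp4a3 (-2.03). Collagens were higher there as well (17 of 17, median 2.09), but Col1a1, Col1a2 and Col3a1, which these cells should lack, together were at 512 CPM in normoxia and 1391 in hypoxia, against 5842 in mesenchymal-like cells of the hypoxic library. Transcripts of another cell type thus differed between the libraries, a limit for every ratio in this class, Ptprd, Ghr and Ptprk included. The median was 0.21 without the cells of highest doublet score.

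In macrophage-like cells at day 10 (119 hypoxic and 183 normoxic), HIF targets had a median of 0.78 (33 of 52 higher, 2 lower), glycolysis 0.14 (-0.069 with each library clustered alone), mitochondrially encoded transcripts -0.49, S phase -1.41 (35 of 40 lower) and cholesterol biosynthesis -0.87. Fibrillar collagens were at 475 CPM in normoxia and 476 in hypoxia in this class, against 7772 and 3114 in mesenchymal-like cells, so relative to that class the background was larger in hypoxia. HIF targets outside glycolysis took 0.395% and 0.584% of UMIs in macrophage-like cells and 0.511% and 1.13% in mesenchymal-like cells, a limit for the HIF and glycolysis medians here. Interferon response genes, which antiviral signalling induces, were higher in this class, 7 of 11 by at least 1.5-fold and 1 lower. Their median was 2.20 (interval 0.16 to 4.60), and 2.20 with Rsad2 set against a floor of 3 counts in normoxia. Rsad2 had 75 UMIs in hypoxia (46.8 CPM) and 0 in normoxia, where 3 counts over the class would be 0.742 CPM. Against that floor it was 63.0-fold higher, a value that leaves out counting error in the 75 UMIs. Usp18 (76 and 4 UMIs, 4.60), Ifit1 (49 and 2, 4.40, interval 4.02 to 9.03) and Ifit3 (48 and 7, 3.50) went the same way. Rsad2, Usp18, Ifit1 and Ifit3 lay below 5 CPM in normoxia and passed the filter only through their hypoxic level. The count and median of the list are thus not independent of the difference. In mesenchymal-like cells at day 10 the median of the list's measured members was below 0, from -1.64 to -1.47 across the alternatives. Members were filtered at 5 CPM within each class, and over whole libraries only 3 were measured. The medians of these classes are thus not over the same genes and are not a like comparison. The highest ratios were in Mmp12, a macrophage elastase gene (103 and 2 UMIs, 5.45, interval 5.13 to 10.09), Pcdh9 (85 and 3 UMIs, 4.95, 4.56 to 8.46) and Rsad2. The scavenger receptor genes Mrc1 (38 UMIs in hypoxia and 4544 in normoxia, -5.51) and Stab1 (13 and 910, -4.63) and Ms4a6c (1 and 259, -5.33, interval -11.99 to -4.19) were lowest. The collagen list was at 0.87 in these cells. It was -0.53 with each library clustered alone, -0.46 with 4000 variable genes and -0.47 with all deposited barcodes, and between 0.34 (highest doublet scores removed) and 0.87 in the other alternatives.

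**Figure D3:**
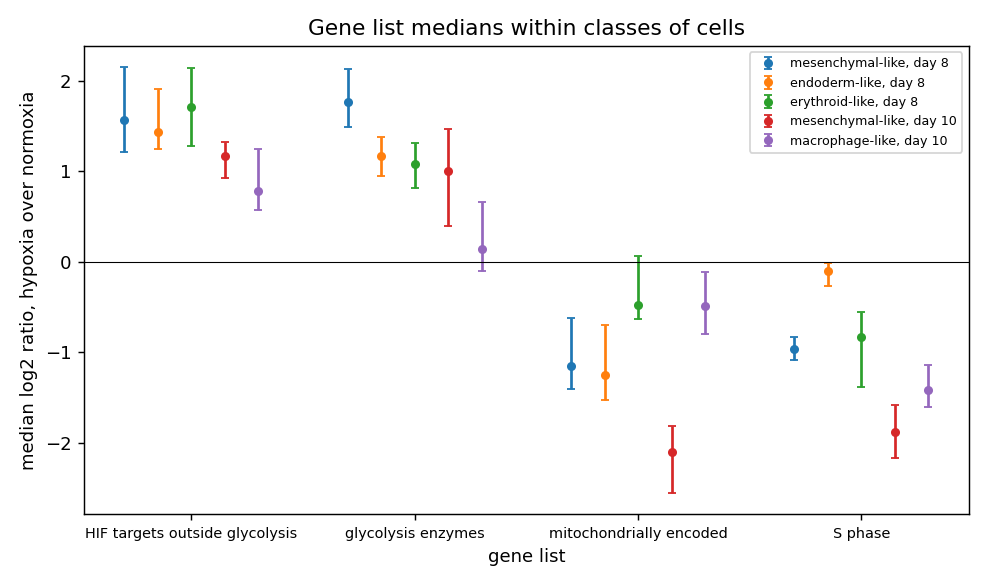
Median log2 ratio of CPM + 1 of each gene list within each class compared, with the interval of the median over members. HIF targets lay between 0.78 and 1.71 in the hypoxia comparisons of the 4 classes.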

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

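No test was chosen for this part after its results were seen, because none was run: the differences below between the day 8 and day 10 hypoxia comparisons were not tested, and each comparison rests on 1 library per group. They stood out because the hypoxic library was at least 1.5-fold above its normoxic partner at 1 age and at least 1.5-fold below it at the other. Only genes named by the rule were searched, so these are not all such genes. Among all 6575 genes, 4 were at least 2-fold higher at day 8 and lower at day 10, and 3 the reverse.

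Higher at day 8 and lower at day 10 were the lipolysis inhibitor gene G0s2 (log2 ratio 2.64 at day 8 and -0.61 at day 10), the neurokine gene Tafa2 (2.54 and -0.99), the appetite hormone gene Ghrl (1.23 and -1.47), the HIF inhibitor gene Hif3a (0.64 and -1.28), the cadherin gene Cdh13 (0.74 and -2.38) and the adhesion molecule gene Ncam1 (0.72 and -1.55). With age in normoxia the log2 ratios of these 6 were 1.38, 2.01, -2.94, 1.16, 2.63 and 0.094.

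Lower at day 8 and higher at day 10 were the imprinted growth regulator gene Phlda2 (-1.26 and 2.05), the chaperone gene Hspa1a (-1.01 and 2.72), the apoptosis gene Pmaip1 (-0.86 and 1.42) and the heart muscle genes Myl3 (-1.33 and 0.77), Myl7 (-1.07 and 1.57) and Myh6 (-0.81 and 1.96). The share of cardiomyocyte-like cells was 0.759% in normoxia and 0.419% in hypoxia at day 8, and 0.337% and 0.932% at day 10. The day 8 ratio, 0.552, has an interval of 0.264 to 1.11 that includes 1. The day 8 hypoxic share was 0.769% without the highest doublet scores, 0.748% at resolution 0.5, 0.806% in cells of at least 10000 UMIs, 0.807% with 4000 variable genes and 4.16% with each library clustered alone. With 4000 variable genes the normoxic share moved too, to 1.20%, so hypoxia stayed lower there. With class shares held constant, the day 10 log2 ratios of Myl3, Myl7 and Myh6 were -1.14, -0.33 and -0.36. These rest on few cells: normoxia at day 10 held 9 cardiomyocyte-like cells, with a median of 1685 UMIs. Hspa1a belongs to genes that dissociation induces, and its highest level was 15.2 CPM. Whether these opposite directions would be seen again with other cultures is open.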

How the results depend on the processing

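Removing the cells of highest doublet score, keeping only cells of at least 10000 UMIs and centring the ratios on the median of all genes were tests chosen after results were seen. In all, 21 alternatives, 18 of them planned, were run, and of 2445 values for results that answer a comparison, 2286 stayed within their interval or, for counts of genes, within 1.5 times the reported count (lists of under 6 members have no interval and a margin of 0.25 was used). Of the 2445, 70 had the opposite sign, 57 of them within that interval or margin. Shares and medians within classes were run only under the alternatives for cells and clusters. Their dependence on scaling was not measured, and the pooled count does not cover it. The medians of HIF targets ranged from 1.21 to 1.80 at day 8 and from 0.91 to 1.56 at day 10, those of glycolysis from 1.55 to 1.83 and from 0.73 to 1.40, and those of S phase genes from -0.94 to -0.62 and from -2.09 to -1.07. Of 11088 values of named genes, 8172 stayed within their counting interval and 2916 moved beyond it. Of the 11088, 195 had the opposite sign, 19 of these for genes reported as at least 1.5-fold different. Given below, with the reported value in parentheses, are the values answering a comparison that moved beyond these limits and, of named genes and marker lists, only those whose reported direction turned from a called value. Apart from the numbers of genes counted under the filters on low genes the cause was not tested. No paired analysis was possible because the labels pair no cultures beyond their age and each group has 1 library. Numbers of cells limit the small classes: 2 endothelial-like and 3 pluripotent-like cells were kept in normoxia at day 10. No value could be had for lists without members under a filter, or for shares of classes that a clustering did not find in both libraries.

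With TMM scaling, 191 (115) at day 8 and 976 (318) at day 10 were at least 2-fold higher, and 14 (60) at day 8 and 653 (1433) at day 10 were at least 2-fold lower. List medians were 1.83 (1.60) for glycolysis, -0.062 (-0.29) for oxidative phosphorylation, 0.021 (-0.20) for citric acid cycle, -0.67 (-0.88) for S phase and -0.18 (-0.40) for G2 and M phase at day 8. List medians were 1.56 (1.06) for HIF targets, 1.40 (0.90) for glycolysis, -0.085 (-0.58) for oxidative phosphorylation, -1.52 (-2.02) for mitochondrially encoded transcripts, -0.16 (-0.66) for citric acid cycle, 0.62 (0.13) for chromatin oxygenases, -1.45 (-1.87) for S phase, 0.87 (0.38) for p53 targets, -0.16 (-0.65) for cholesterol biosynthesis and -0.86 (-1.35) for interferon response at day 10. List medians were -0.042 (-0.17) for oxidative phosphorylation, 0.073 (-0.048) for citric acid cycle and -0.16 (-0.28) for G2 and M phase with age. With no filter on low genes, which counts more genes, 243 (115) at day 8, 644 (318) at day 10 and 612 (173) with age were at least 2-fold higher, and 357 (60) at day 8, 3819 (1433) at day 10 and 545 (113) with age were at least 2-fold lower. The list median was -0.28 (-0.72) for interferon response at day 8. List medians were -0.59 (-1.35) for interferon response, -0.11 (0.84) for surface ectoderm markers and 0.12 (-0.93) for nephric mesoderm markers at day 10. List medians were 0.48 (1.17) for interferon response and -0.087 (0.82) for hemogenic progenitor markers with age. Pearson r across genes was 0.38 (0.44). With genes of at least 50 CPM, which are fewer, 70 (115) at day 8, 186 (318) at day 10 and 89 (173) with age were at least 2-fold higher, and 17 (60) at day 8, 602 (1433) at day 10 and 46 (113) with age were at least 2-fold lower. The list median was -0.78 (-0.88) for S phase at day 8. The list median was -0.074 (-0.98) for heme biosynthesis at day 10. With a pseudocount of 10 CPM, 21 (60) at day 8, 940 (1433) at day 10 and 63 (113) with age were at least 2-fold lower. List medians were 1.21 (1.59) for HIF targets, -0.62 (-0.88) for S phase, -0.33 (-0.40) for G2 and M phase and -0.34 (-0.72) for interferon response at day 8. List medians were -1.07 (-1.87) for S phase and -0.70 (-1.35) for interferon response at day 10. The list median was 0.92 (1.17) for interferon response with age. With cells thinned to the same depth, the list median was -0.98 (-0.72) for interferon response at day 8. Pearson r across genes was 0.39 (0.44). With ratios centred on the median of all genes, 664 (318) at day 10 were at least 2-fold higher, and 867 (1433) at day 10 were at least 2-fold lower. Without the most extreme member of a list, the list median was -1.04 (-1.35) for interferon response at day 10. The list median was 0.87 (1.17) for interferon response with age. With class shares held constant, list medians were 0.040 (-0.43) for heme biosynthesis, 0.12 (-3.05) for hemoglobin and 0.20 (-2.21) for erythroid markers with age. For erythroid, cardiac and endothelial genes this setting rests on few cells. Normoxia at day 10 held 11, 9 and 2 cells of those classes. Signs changed at day 10 for Spi1 0.013 (-1.45), Actc1 -0.78 (1.91), Apoc2 0.0090 (-0.61), Myl3 -1.14 (0.77), Myl7 -0.33 (1.57), Tnnc1 -0.022 (0.63), Myh6 -0.36 (1.96) and Rbp4 0.079 (-0.92). Signs changed with age for Ttn 0.25 (-2.06), Actc1 0.20 (-2.48), Car2 0.21 (-1.80), Flt1 0.20 (-0.69), Hbb-bs 1.25 (-1.92), Hbb-y 0.12 (-3.05), Hba-a1 1.21 (-1.97), Hba-a2 1.42 (-1.73), Myh6 0.66 (-1.70), Slc25a37 0.32 (-1.20) and Alas2 0.20 (-2.21). With a total that left out mitochondrial, ribosomal protein and hemoglobin genes, the list median was -0.12 (-0.17) for oxidative phosphorylation with age. With cells of equal weight, Pearson r across genes was 0.40 (0.44).

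With all deposited barcodes, mesenchymal-like cells made up 80.2% (84.9) in normoxia at day 8, 83.1% (86.8) in hypoxia at day 8, 84.8% (89.5) in normoxia at day 10 and 71.0% (93.5) in hypoxia at day 10. Endothelial-like cells made up 0.297% (0.569) in normoxia at day 8 and 0.190% (0.498) in hypoxia at day 10. The log2 ratio of shares was -0.26 (0.063) for mesenchymal-like cells at day 10. The median within mesenchymal-like cells was -0.92 (-0.36) for hemoglobin at day 8. The median within macrophage-like cells was -0.47 (0.87) for collagens at day 10. The median within erythroid-like cells was 2.35 (2.09) for collagens at day 8. With cells of at least 10000 UMIs, mesenchymal-like cells made up 86.4% (84.9) in normoxia at day 8, 88.6% (86.8) in hypoxia at day 8, 91.1% (89.5) in normoxia at day 10 and 95.8% (93.5) in hypoxia at day 10. Endoderm-like cells made up 0.661% (1.19) in hypoxia at day 10. Erythroid-like cells made up 2.78% (3.45) in normoxia at day 8, 3.02% (4.55) in hypoxia at day 8 and 0.0330% (0.217) in hypoxia at day 10. Megakaryocyte-like cells made up 0.762% (1.11) in normoxia at day 8, 0.0418% (0.412) in normoxia at day 10 and 0.132% (0.953) in hypoxia at day 10. Cardiomyocyte-like cells made up 0.806% (0.419) in hypoxia at day 8, 0.0836% (0.337) in normoxia at day 10 and 0.595% (0.932) in hypoxia at day 10. Endothelial-like cells made up 0.331% (0.569) in normoxia at day 8 and 0.165% (0.498) in hypoxia at day 10. Pluripotent-like cells made up 0% (0.474) in normoxia at day 8, 0% (0.449) in hypoxia at day 8, 0% (0.112) in normoxia at day 10 and 0% (0.130) in hypoxia at day 10. Log2 ratios of shares were -1.69 (-0.96) for endoderm-like cells at day 10, -3.34 (-0.93) for erythroid-like cells at day 10, -4.19 (-1.43) for megakaryocyte-like cells with age, 2.83 (1.47) for cardiomyocyte-like cells at day 10 and -3.57 (-1.17) for cardiomyocyte-like cells with age. The median within endoderm-like cells was -1.47 (-1.88) for interferon response at day 8. With at least 1500 genes and at most 10% mitochondrial UMIs, mesenchymal-like cells made up 88.2% (86.8) in hypoxia at day 8, 90.9% (89.5) in normoxia at day 10 and 95.4% (93.5) in hypoxia at day 10. Endoderm-like cells made up 0.711% (1.19) in hypoxia at day 10. Erythroid-like cells made up 2.81% (3.45) in normoxia at day 8, 3.38% (4.55) in hypoxia at day 8 and 0% (0.217) in hypoxia at day 10. Megakaryocyte-like cells made up 0.221% (0.953) in hypoxia at day 10. Cardiomyocyte-like cells made up 0.0797% (0.337) in normoxia at day 10. Endothelial-like cells made up 0.221% (0.498) in hypoxia at day 10. Log2 ratios of shares were -0.11 (1.21) for megakaryocyte-like cells at day 10, 3.30 (1.47) for cardiomyocyte-like cells at day 10 and -3.65 (-1.17) for cardiomyocyte-like cells with age. The median within mesenchymal-like cells was -0.82 (-0.36) for hemoglobin at day 8. With each library clustered alone, mesenchymal-like cells made up 84.2% (86.8) in hypoxia at day 8. Endoderm-like cells made up 4.10% (5.23) in hypoxia at day 8. Macrophage-like cells made up 5.66% (6.85) in normoxia at day 10. Erythroid-like cells made up 0.787% (0.412) in normoxia at day 10 and 1.21% (0.217) in hypoxia at day 10. Megakaryocyte-like cells made up 0% (0.412) in normoxia at day 10 and 0% (0.953) in hypoxia at day 10. Cardiomyocyte-like cells made up 4.16% (0.419) in hypoxia at day 8 and 0% (0.337) in normoxia at day 10. Endothelial-like cells made up 1.74% (0.569) in normoxia at day 8 and 0% (0.0749) in normoxia at day 10. Pluripotent-like cells made up 0% (0.112) in normoxia at day 10 and 0% (0.130) in hypoxia at day 10. Log2 ratios of shares were -0.79 (-0.45) for endoderm-like cells at day 8, 0.63 (-0.93) for erythroid-like cells at day 10, -1.89 (-3.06) for erythroid-like cells with age, 2.58 (-0.86) for cardiomyocyte-like cells at day 8 and -1.69 (-0.080) for endothelial-like cells at day 8. Medians within mesenchymal-like cells were 0.35 (-0.36) for hemoglobin at day 8 and -3.63 (-3.88) for hemoglobin with age. Medians within macrophage-like cells were 0.54 (0.78) for HIF targets at day 10, -0.55 (-0.69) for oxidative phosphorylation at day 10 and -0.53 (0.87) for collagens at day 10. With 4000 variable genes, mesenchymal-like cells made up 89.1% (93.5) in hypoxia at day 10. Cardiomyocyte-like cells made up 1.20% (0.759) in normoxia at day 8 and 0.807% (0.419) in hypoxia at day 8. Pluripotent-like cells made up 0% (0.474) in normoxia at day 8, 0% (0.449) in hypoxia at day 8, 0% (0.112) in normoxia at day 10 and 0% (0.130) in hypoxia at day 10. The median within mesenchymal-like cells was 0.32 (-0.36) for hemoglobin at day 8. The median within endoderm-like cells was -1.51 (-1.88) for interferon response at day 8. The median within macrophage-like cells was -0.46 (0.87) for collagens at day 10. Without the cells of highest doublet score, cardiomyocyte-like cells made up 0.769% (0.419) in hypoxia at day 8. The median within endoderm-like cells was -0.010 (-0.11) for S phase at day 8. The median within macrophage-like cells was 0.34 (0.87) for collagens at day 10. Medians within erythroid-like cells were -0.98 (-0.75) for G2 and M phase at day 8, -1.25 (-0.76) for immediate early genes at day 8 and 0.21 (2.09) for collagens at day 8. At a resolution of 0.5, cardiomyocyte-like cells made up 0.748% (0.419) in hypoxia at day 8. With doublet calls kept, at a resolution of 2, and with response genes kept in the clustering alike, endothelial-like cells made up 0.316% (0.569) in normoxia at day 8 and 0.173% (0.498) in hypoxia at day 10. Collagens in macrophage-like cells at day 10 were at 0.67 (0.87) with doublet calls kept and 0.52 (0.87) with response genes kept, where hemoglobin in mesenchymal-like cells was at -3.51 (-3.88) with age.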

Other observations

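The tests of lost cytoplasm and, for genes lower after 48 h, of cells nearer in depth, of abundant transcripts and of TMM scaling were chosen after the results they measure were seen, and so was the list of small nucleolar RNA (snoRNA) host genes. As shares of all UMIs, HIF targets outside glycolysis took 0.528% in normoxia and 1.38% in hypoxia at day 8, and 0.507% and 1.11% at day 10, while glycolysis enzymes took 0.532% and 1.63%, and 0.472% and 1.09%. S phase genes took 0.217% and 0.114%, and 0.166% and 0.0551%, and G2 and M phase genes 0.562% and 0.408%, and 0.434% and 0.205%. The platelet chemokine gene Ppbp, of the megakaryocyte list, was at 0.900 CPM in normoxia and 24.5 in hypoxia at day 10 (log2 ratio 3.74), while the platelet factor gene Pf4 was at 17.6 and 8.59 CPM (-0.96). The keratin genes Krt19 (72.3 and 309 CPM, 2.08) and Krt18 (209 and 613 CPM, 1.54) were higher after 48 h of hypoxia, as was the transcription factor gene Gata3 (3.31 and 21.9 CPM, 2.41). The keratins were also higher at day 8 (1.73 and 0.78).

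Mitochondrially encoded transcripts were lower in both hypoxia comparisons. Fewer UMIs per cell as the whole cause is argued against by cells nearer in depth: in mesenchymal-like cells of 10000 to 30000 UMIs (medians 15350.5 in hypoxia and 19128 in normoxia) the median log2 ratio at day 10 was -2.21 (interval -2.50 to -1.84). Barcodes that lost cytoplasm would have lower ribosomal protein transcripts too, but these had a median of 0.48 (0.39 to 0.55) at day 10, which argues against such loss as the whole cause. The nuclear RNA Malat1, which such loss would raise, was at 16092 CPM in normoxia and 27236 in hypoxia, so some loss is not excluded. A lower level of mitochondrial transcripts in hypoxic cells stays open as a hypothesis that was not tested, since library and condition cannot be told apart.

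Many genes were lower after 48 h of hypoxia: after subtracting the median ratio of genes of like length, 55.8% (53.2 to 58.4) of the 1433 genes at least 2-fold lower were still so, against 60.5% after subtracting the median of all genes and 85.5% when the length trend alone was removed, so length was not the whole cause; the longest 10% of genes had a median of -1.01 and the shortest 10% -0.29. Between cells of 10000 to 30000 UMIs (2439 in hypoxia and 1802 in normoxia, medians 15296 and 19060 UMIs), 93.6% (92.3 to 94.9) were still lower, which argues against depth per cell as the whole cause. The 1433 genes were chosen from sums that include these cells, so this percentage was in part fixed in advance. Leaving mitochondrial, ribosomal protein and hemoglobin genes and the 50 most abundant genes of either library out of the total left 77.0% (74.7 to 79.1) of the 1433 lower and TMM scaling 48.2% (45.6 to 50.8). The share depends on the scaling, so abundant transcripts taking more of the total cannot be told apart from lower levels of the genes themselves. A response of the cells to hypoxia remains open and was not tested.

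The snoRNA host genes Snhg12 and Snhg16 were among the highest ratios at day 10, and the hosts as a list were higher: 11 of 16 at least 1.5-fold higher and 1 lower (median 1.03, interval 0.53 to 1.72), with Snhg1 at 169 and 969 CPM (2.52) and Gas5 at 359 and 1186 (1.72), against a median of 0.11 at day 8. The day 10 median lay at the 100th percentile of random lists matched on expression and length. Snhg12 and Snhg16 prompted the list in this same comparison and stay in it, so this percentile is a description and not independent evidence against short gene length. Matched on expression alone, the list was also at the 97.77th percentile at day 8 and at the 98.99th with age in normoxia (median 0.19). Transcripts of these hosts are known targets of nonsense-mediated decay, so weaker decay may raise them; transcripts of 9 decay factors, which that state is known to raise, had a median of -0.15 at the 80.35th percentile of matched lists, which leaves this undecided.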
